A study of Oryza sativa with 12 samples.

How the data were processed

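Gene expression was measured on Affymetrix rice genome arrays in 12 leaf samples of 4 groups, 2 cultivars with and without drought, with 3 arrays each. Groups were taken from the cultivar and stress labels and replicate numbers from the label of the biological replicate. The labels' protocols state Trizol extraction of total RNA, a clean-up step, and biotin labelling from 6 µg of total RNA. The deposited values are linear signal intensities for each probe set and array, and the submitters' processing notes name MAS5. The scaling target, the software version and detection calls are not given in the sources used here. Medians and trimmed means differed between arrays (2% trimmed mean 89.47 to 123.6), so the values show no scaling to a shared target over all probe sets. No pair of arrays held mostly identical values (0 pairs), and no sample was left out.

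The values were used as deposited, as log2(signal + 16). Probe sets above their own array's median in at least 3 of 12 arrays were tested, 33476 in all, and the 123 control probe sets were left out. A linear model with 1 mean per group over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with 6 contrasts: the drought response in each cultivar, their mean, their difference (interaction), and the cultivar difference in control and in drought. P-values were adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. Tables were handled with the data.table package (1.17.8) and pandas 2.3.3 and plots drawn with matplotlib 3.10.9. The labels call the replicates biological, and the series' design text gives 1 bag of leaves per block in 3 field blocks, with leaves of 2 plots per block in drought and of 1 plot in control. No label ties a replicate number to a block.

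Probe sets were named through the platform's gene table and a table of the species' genes: 22436 of 57381 probe sets had 1 gene, 95 several and 34850 were not listed. Of 17905 genes, 2430 had a name other than a bare identifier, and only these could be named. For a gene with several probe sets the one with the highest mean log2 value was used. Of 44 list themes written before the data were examined, 41 had members. The tables hold symbols and synonyms but no descriptions, so the themes were turned into symbol patterns after gene names had been seen and before any gene's value was read, and 16 further lists were added at the same stage, among them beta-glucosidases, calcium-dependent kinases, calmodulin-like proteins, kinesins, germin-like proteins and metallothioneins. Lists with at least 5 measured genes, 51 of 57, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, under which no list was called in any contrast. P-values were adjusted over the 51 lists within a contrast. The direction of every called list was the same under quantile normalization and median centring. Of the 16 added lists, these 6 and no others were called in any contrast. Counts of members that rose or fell are over all genes tested, and the counts adjusted over the list alone were the same except where the text gives them. Lists with under 5 measured genes, namely those of anther, root, carbon fixation, flavonoid, ABA synthesis and lipid transfer genes, were not tested.

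Genes were named by a rule fixed before the data were examined: among called genes whose arrays do not overlap, the 12 largest rises and falls in each drought response and the 8 largest each way in the interaction and the cultivar differences, and up to 4 members per list described. Names shown for 4 genes (salT, PPDK2, ATG8D and RBBI3.3) replaced other synonyms of the same gene after the values were seen, without changing which genes were selected. No detection calls were used, so the highest of 33 negative control probe sets on each array served as background, and lower bounds compare the bright group with the higher of background and the dim probe set's own signal. A group counted as at background if all its arrays were or, as chosen after values were seen, if its mean signal was no higher than the mean background of its arrays.

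The pipeline was tested on simulated data with 200 of 33476 probe sets changed. At a log2 change of 0.5 it recovered at most 16.4% in any contrast (the mean). At a log2 change of 1 it recovered 58.2% of changed probe sets for the Azucena response, 50.7% for the Bala response, 82.1% for the mean, 25.4% for the interaction, 62.7% for the control cultivar difference and 67.2% for the drought cultivar difference, and at a log2 change of 2 it recovered 97%, 93.9%, 100%, 83.3%, 98.5% and 98.5%. In the data 3794 to 13165 probe sets were called per contrast, so that larger unadjusted p-values passed the threshold than in the simulation. The recovery rates therefore do not give the sensitivity in the data. The list test was tested on simulated data for the Bala response over 15608 genes. The first list left unshifted had an adjusted p of 0.049. Of 200 further unshifted lists 2 (1%) had p under 0.05 and 0 were called after adjustment. Values were drawn independently for each gene, so this rate does not hold for lists whose genes move together.

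Alternatives planned beforehand were pseudocounts of 1 and 64, no filter, the brighter of 2 equal parts of the probe sets by mean, quantile normalization, median centring, the replicate number as a block, no trend, array weights, only the groups compared, 1 probe set per gene, fry for lists, an estimated correlation and leaving out each array. Centring on 63 spike-in probe sets was chosen after seeing the data.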

Results

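The study compared leaf gene expression in field-grown rice (Oryza sativa) with and without drought in 2 cultivars, Azucena, an upland tropical japonica type, and Bala, an upland indica type. Plants grew in flooded plots, and from day 59 after sowing water was withheld from some plots while control plots stayed flooded. Leaves were sampled on day 83, after 24 days without water. The youngest but one of the fully expanded leaves was used, and its central part, with 4 cm removed at each end, was frozen. Leaves were pooled into 1 bag per field block, and the drought bags drew on more plots per block than the control bags. Total RNA was hybridised to Affymetrix rice arrays, 1 array per sample, with 3 biological replicates in each of the 4 groups and 12 arrays in all. Each array gave a signal for 57381 probe sets, with a median signal between 9.6 and 12.4. The highest negative control probe set, used here as the background level, lay between 13.4 and 28.3. Replicate arrays of a group correlated at 0.95 to 0.97 (Spearman, across probe sets), arrays of the same cultivar in the other condition at 0.87 to 0.9, and arrays of the other cultivar in the same condition at 0.85 to 0.88. The ratio of 3′ to 5′ probe set signal, a sign of RNA quality, was 7.05 ± 0.4 for actin in Azucena control, 6.64 ± 0.093 in Azucena drought, 6.58 ± 1.3 in Bala control and 6.63 ± 0.42 in Bala drought (SD, n = 3 each). For ubiquitin it was 0.69 ± 0.012, 0.68 ± 0.039, 0.73 ± 0.036 and 0.7 ± 0.024 in the same order. Actin and ubiquitin thus differed widely in this ratio, which therefore does not show whether the RNA was intact. Signals below are group means ± SD with n = 3, fold changes are on the log2(signal + 16) scale, which understates the change of dim genes, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. Where a group lay at or under background on all its arrays or in its mean, the change is given as a lower bound against the background level. An interaction value of such a gene depends on the added 16 and is no bound. Lower bounds cannot be compared between cultivars or conditions whose background levels differ. The number of arrays limits the precision. Rankings of single genes below cover only called genes with a name, which 2430 of 17905 genes had. An unnamed gene may therefore exceed those ranked.

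The first comparison asked how Azucena leaves changed under drought. Among genes with a name, the largest rises were mostly in genes of water-deficit and heat protection. RAB21 (LOC4350454), a dehydrin, rose from a signal of 23.7 ± 20, no higher than background, to 8160 ± 51, at least 284-fold (adjusted p = 6.3e-12). The dehydrin gene RAB16B rose at least 164-fold, to 3890 ± 110, and the late embryogenesis abundant (LEA) gene LEA19 at least 83.7-fold, to 1990 ± 230. Small heat shock protein genes rose as well, among them HSP26.7 (at least 190-fold), HSP23.2 (at least 71.8-fold), HSP18.1 (86.4-fold), HSP16.9A (66.4-fold), HSP16.9B (34.5-fold) and HSP17.4 (33.4-fold). Their drought signals varied widely between arrays, as in HSP26.7 with 4880 ± 2500. RAB16C rose 31.9-fold, PXG at least 62.3-fold, and salT, a mannose-binding lectin, at least 69.7-fold, with signals of 880.7, 5760.5 and 887.6 on the 3 drought arrays. The largest falls were in AT5 (log2 change -4.28, from 726 ± 150 to 22.5 ± 9.9) and mfs1 (-4.13, from 1900 ± 680 to 91.7 ± 24). RPP17-1 fell from 286 ± 39 to background, at least 13.1-fold, and LOGL10, a cytokinin-activating enzyme gene, at least 12.4-fold. MADS14, a floral identity factor, had a log2 change of -3.71. The auxin transporter gene PIN5A (-3.64), the metallothionein gene MT2B (-3.39) and Rcb4 (-3.28) fell too. So did the actin-depolymerising factor gene ADF-11 (-3.15), the lipoxygenase genes LOX8 (-3.11) and LOX9 (-2.97), and the heat stress factor gene HSFA4D (-3.02).

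Counts for gene lists are over all genes tested unless said otherwise. Of these lists, 7 of 8 LEA and dehydrin genes rose in Azucena and none fell, with a median log2 change 3.59 above that of all genes (camera, adjusted p = 2.1e-07; adjusted p = 0.62 with an estimated correlation). In ABA signalling, 14 of 20 genes rose and 1 fell (adjusted p = 1.4e-05; adjusted p = 0.64 with an estimated correlation). Adjusted over the list alone 15 rose and 1 fell. These included PP2C68 (10.5-fold), OsPP2C51 (at least 13.8-fold) and OsPP2C09 (5.6-fold), protein phosphatases of the ABA pathway, and the transcription factor gene OsBZIP23, which went from 255 ± 14 to 1480 ± 81. Among 39 heat shock protein and factor genes, 19 rose and 4, HSFA4D among them, fell (adjusted p = 0.00014; adjusted p = 0.7 with an estimated correlation). Adjusted over the list alone the counts were 22 and 5. Of 5 genes of chlorophyll breakdown and leaf senescence 4 rose (adjusted p = 0.044; adjusted p = 0.69 with an estimated correlation). SGR, which acts in chlorophyll degradation, led with a rise from 301 ± 140 to 1990 ± 980. The rise of the last of these, NYC1 (0.73), was not called without Azucena drought 2 (adjusted p = 0.078). Of 16 chlorophyll synthesis genes 6 fell, among them URO-D2, PORA and CHLH, and none rose (adjusted p = 0.036; adjusted p = 0.78 with an estimated correlation), with 7 lower adjusted over the list alone. Of 23 beta-glucosidase genes, a list added after gene names were seen, 12 rose and 2 fell (adjusted p = 0.02; adjusted p = 0.67 with an estimated correlation). BGLU32 rose 4.02-fold and BGLU36 4.07-fold, and BGLU12 stood at -2.84. The chlorophyll breakdown list was not called without Azucena control 2, Bala control 1 or 3 or Azucena drought 2 or 3 (adjusted p between 0.055 and 0.082), nor under quantile normalization (0.069) or median centring (0.057). That of chlorophyll synthesis was not called without Azucena control 1 or 2 or Azucena drought 2 or 3 (0.056 to 0.082), nor under quantile normalization (0.056).

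Other groups had more falls than rises in Azucena. In diterpene phytoalexin synthesis 9 of 14 genes fell (10 adjusted over the list alone) and none rose (adjusted p = 0.0011; adjusted p = 0.64 with an estimated correlation). OsMAS fell at least 3.15-fold and CYP99A2 at least 5.46-fold. In cytokinin synthesis, breakdown and response 13 of 22 genes fell (14 adjusted over the list alone) and 4 rose (adjusted p = 0.0075; adjusted p = 0.69 with an estimated correlation). LOGL10, LOGL9 (-1.81) and the response regulator gene RR9 (-2.67) led. Among calcium-dependent kinases, a list added after names were seen, 8 of 19 fell and 1 rose, with CPK13 at -1.84 and CPK4 at -1.77 (adjusted p = 0.0088; adjusted p = 0.67 with an estimated correlation). In calmodulin-like proteins, likewise added, 11 of 24 fell (12 adjusted over the list alone) and 1 rose, with CML27 at -2.3 (adjusted p = 0.0088; adjusted p = 0.69 with an estimated correlation). In jasmonate synthesis and response 11 of 26 fell and 1 rose, led by TIFY10B (-1.63), LOX9 and LOX8 (adjusted p = 0.024; adjusted p = 0.76 with an estimated correlation). Adjusted over the list alone 13 fell and 4 rose. Of 22 genes commonly used as expression references, 8 fell (9 adjusted over the list alone) and none rose, including UBQ4 (-1.03) and TUBB2 (-1.34) (adjusted p = 0.031; adjusted p = 0.78 with an estimated correlation). Lignin and phenylpropanoid genes fell in 6 of 13 cases, led by CAD6 (-2.64), CAD2 (-2.07) and CAD3 (-1.43), cinnamyl alcohol dehydrogenase genes (adjusted p = 0.036; adjusted p = 0.67 with an estimated correlation). Iron homeostasis genes fell in 11 and rose in 4 of 25 cases, led by YSL12 (-2.2) and YSL16 (-2.69), metal-chelate transporter genes (adjusted p = 0.041; adjusted p = 0.76 with an estimated correlation). The lignin list was not called without Azucena control 3 (adjusted p = 0.072) or Azucena drought 2 (0.063), under quantile normalization (0.069) or under median centring (0.063). The iron list was not called without Azucena control 1 (0.069), under quantile normalization (0.083) or under median centring (0.085), and the reference gene list not without Azucena control 2 (0.1) or Azucena drought 3 (0.052).

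In all, 9190 of 33476 probe sets tested were called in Azucena, 4759 higher and 4431 lower, and, taking 1 probe set for each gene, 5560 of 15608 genes. The share of higher calls was 51.8% as deposited, 49.9% after quantile normalization, 47.9% after median centring and 55.9% after spike-in centring. Which direction held more calls thus depended on the scaling. In 51.4% of the 15608 genes the drought and control arrays did not overlap, against 10% by chance for 3 against 3.

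**Figure D1:**
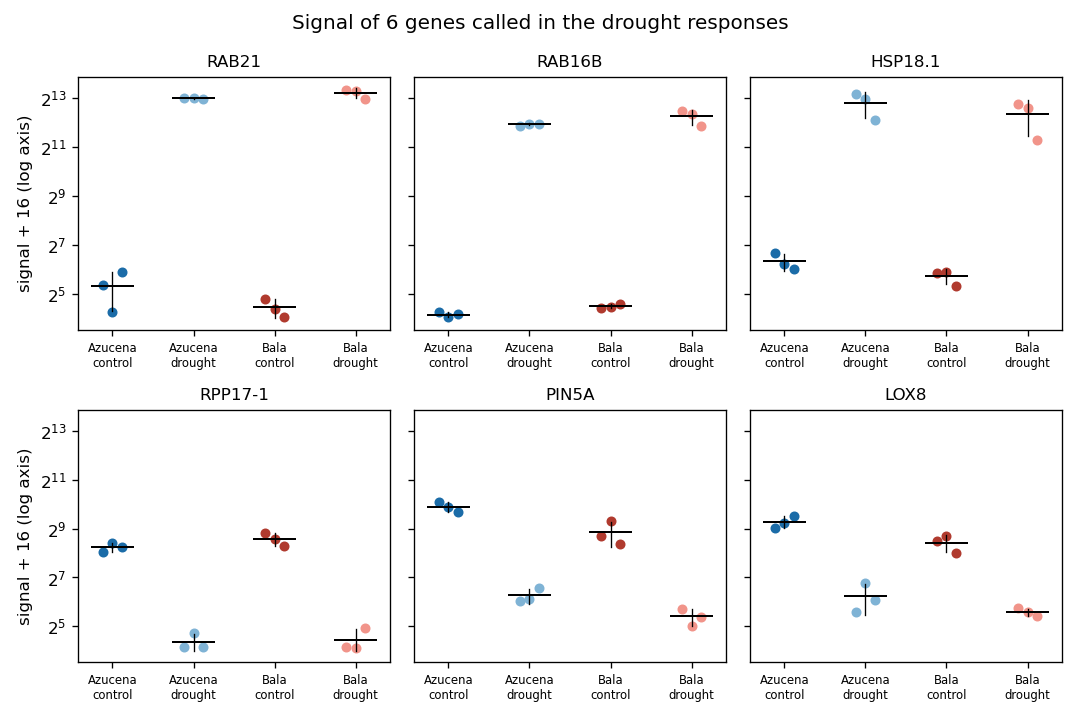
Signal plus 16 on a log axis for 6 genes in the 4 groups; each point is 1 array, the horizontal line is the group mean and the vertical line ± 1 SD (n = 3). RAB21, RAB16B and HSP18.1 lay higher under drought and RPP17-1, PIN5A and LOX8 lower, in both cultivars, with no overlap between drought and control arrays.

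Among genes with a name, the same comparison in Bala gave rises led by many of those that led in Azucena. RAB21 rose at least 628-fold, to 9540 ± 1300, RAB16B at least 318-fold, LEA19 at least 192-fold, HSP26.7 at least 317-fold and HSP17.4 at least 192-fold. Higher bounds than in Azucena partly reflect the lower background, which averaged 15.3 in Bala control and 24 in Azucena control. The log2 changes in Azucena and Bala were 7.83 and 8.8 for RAB21 and 7.78 and 7.74 for RAB16B. They were 6.9 and 7.36 for LEA19 and 7.76 and 7.88 for HSP26.7. None of RAB21, RAB16B, LEA19 and HSP26.7 had a called interaction. HSP18.0 (LOC4325342) rose 135-fold, from 31.2 ± 8.9 to 6790 ± 2900, HSP18.1 92.1-fold, HSP16.9A 76.1-fold, HSP23.2 at least 78.3-fold, HSP18.6 50.9-fold and RAB16C 40.8-fold. CHS1 (LOC4350636), chalcone synthase of the flavonoid pathway, rose 72.7-fold in Bala, from 33.5 ± 12 to 3520 ± 170 (log2 change 6.18, SE 0.18, adjusted p = 3.7e-13). The largest falls were in AT5 (-4.49), RPP17-1 (at least 16.6-fold), the CASP-like gene OsCASPL1U2 (-3.66), BGLU12 (at least 15.5-fold) and Hd3a, the florigen gene, which fell from 322 ± 150 to background (at least 13.8-fold). The germin-like gene RGLP1 fell at least 11.2-fold, and WRKY24 at least 11.1-fold, and PIN5A (-3.42) fell too. The sugar transporter gene MST3 (-3.12), the phosphate transporter gene PHT1-1 (-3.09), LSD1 (-3.07) and Rcb4 (-3.01) followed.

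In Bala the median change over all probe sets tested was 0.13 on the log2 scale as deposited, 0.019 after quantile normalization, -0.046 after median centring and 0.18 after spike-in centring. List medians are given relative to that of all genes. LEA and dehydrin genes rose in 7 of 8 cases, with a median 4.94 above that of all genes (adjusted p = 3.5e-07; adjusted p = 0.48 with an estimated correlation). ABA signalling genes rose in 13 (14 adjusted over the list alone) and fell in 2 of 20 cases (adjusted p = 0.00014; adjusted p = 0.49 with an estimated correlation). OsPP2C51 rose at least 25.6-fold, OsPP2C06 9.5-fold, PP2C68 10.9-fold and OsPP2C09 6.45-fold. Heat shock protein and factor genes rose in 21 and fell in 4 of 39 cases (adjusted p = 0.0014; adjusted p = 0.75 with an estimated correlation). Cellulose synthesis genes rose in 11 of 13 cases (12 adjusted over the list alone) and fell in none (adjusted p = 0.00057; adjusted p = 0.49 with an estimated correlation). Examples were BC1L6 (at least 3.8-fold), CESA1 (4.63-fold), CESA6 (2.76-fold) and CESA4 (at least 6.84-fold). Beside them, 8 of the 12 marker genes of vascular and secondary wall tissue rose and 2 fell in Bala, a list that was not called (adjusted p = 0.27). CESA4, CESA7 and CESA9 belong to both lists, and of the other 9 markers 5 rose and 2 fell. In osmoprotectant and raffinose synthesis 7 of 11 genes rose and 1 fell (2 adjusted over the list alone; adjusted p = 0.016; adjusted p = 0.57 with an estimated correlation). The proline synthesis genes P5CS2 (19.9-fold) and P5CS1 (4.66-fold), the raffinose synthase gene RFS (11.6-fold) and the betaine aldehyde dehydrogenase gene BADH1 (3.33-fold) rose. Antioxidant enzyme genes rose in 17 and fell in 2 of 22 cases (adjusted p = 0.019; adjusted p = 0.75 with an estimated correlation). The superoxide dismutase genes SodCc2 (3.81-fold) and sodCp (2.33-fold) rose, and the catalase gene CAT-A stood at -1.03. Genes of kinesins, motor proteins of microtubules and a list added after names were seen, rose in 15 (16 adjusted over the list alone) and fell in 1 of 27 cases, with KIN13B up at least 5.8-fold (adjusted p = 0.017; adjusted p = 0.75 with an estimated correlation). Beside them, 2 of 9 histone and cell division genes, markers of dividing cells, rose and 1 fell (adjusted p = 1).

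The lists that fell in Bala were led by jasmonate synthesis and response, with 14 of 26 genes lower and 1 higher (adjusted p = 6.6e-05; adjusted p = 0.49 with an estimated correlation). TIFY10B (-1.45), LOX8 (-2.82) and LOX9 (at least 4.22-fold lower) led. Cytokinin genes fell in 12 and rose in 2 of 22 cases, with LOGL9 (-2.17) and LOGL10 (at least 5.25-fold lower) (adjusted p = 0.00012; adjusted p = 0.48 with an estimated correlation). Phytoalexin synthesis genes fell in 10 and rose in 1 of 14 cases, with CYP701A8 at -1.8 (adjusted p = 0.00026; adjusted p = 0.48 with an estimated correlation). Calcium-dependent kinases fell in 8 of 19 cases and rose in none, with CPK4 at -1.96 and CPK13 at -1.68 (adjusted p = 0.00034; adjusted p = 0.48 with an estimated correlation). Photorespiration genes fell in 3 of 5 cases, with GLO4 (-1.77) and GDCSH (-1.32) (adjusted p = 0.016; adjusted p = 0.57 with an estimated correlation). Of 5 germin-like genes, a list added after names were seen, GER7 (at least 7.3-fold) and GER6 (at least 8.33-fold) fell (adjusted p = 0.017; adjusted p = 0.48 with an estimated correlation). Of 6 WRKY transcription factor genes 3 fell, namely WRKY24, WRKY71 (-1.84) and WRKY51 (-1.14) (adjusted p = 0.021; adjusted p = 0.57 with an estimated correlation). Iron homeostasis genes fell in 8 and rose in 4 of 25 cases, with YSL13 at -2 and YSL12 at -1.71 (adjusted p = 0.029; adjusted p = 0.75 with an estimated correlation). Under quantile normalization the calls of photorespiration (adjusted p = 0.058), germin-like proteins (0.058), WRKY factors (0.065) and iron (0.058) were lost, and under median centring those of WRKY factors (0.072) and iron (0.058). The iron list was also not called without Bala control 2 (0.05 after rounding).

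In Bala 10567 probe sets were called, 6912 higher and 3655 lower, and 6465 genes. The share of higher calls, 65.4% as deposited, was 50.7% after quantile normalization, 46% after centring each array on its median and 70.7% after centring on the spike-in controls. The balance of rises and falls thus depended on the scaling. Drought and control arrays did not overlap in 51.7% of the 15608 genes, against 10% by chance.

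**Figure D2:**
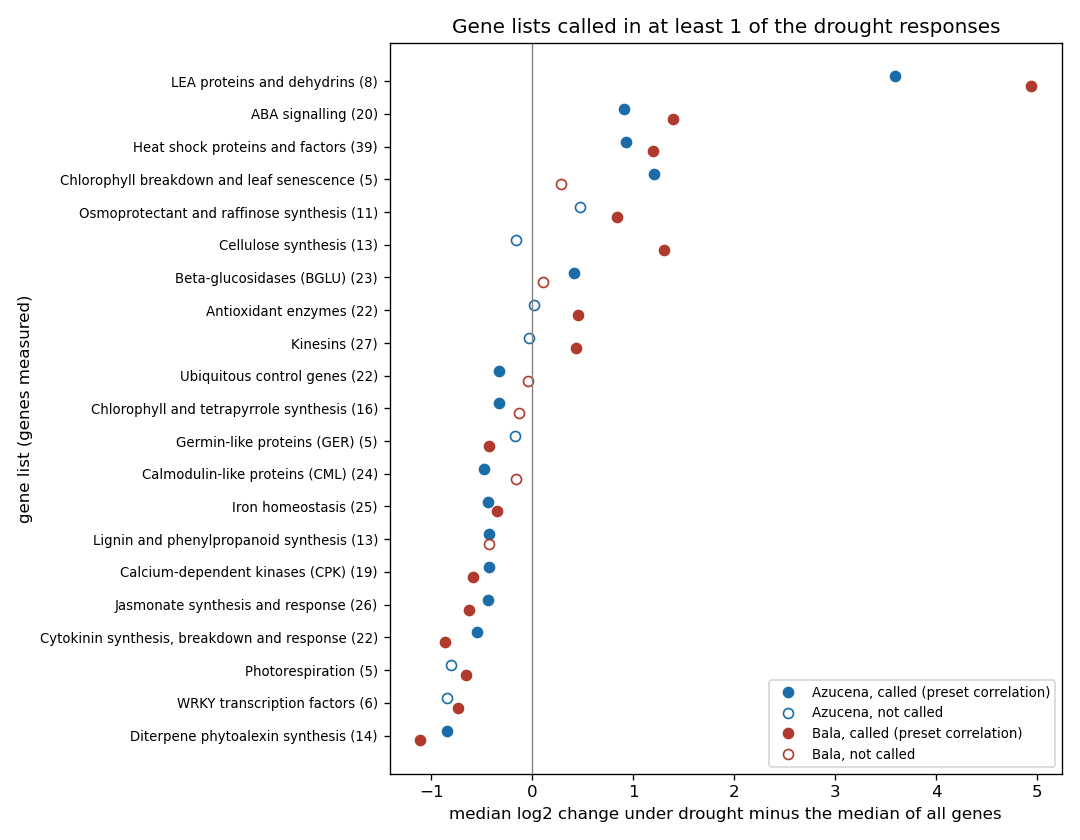
Median log2 change under drought minus that of all genes (horizontal axis) for the 21 gene lists called in at least 1 cultivar, with the number of genes measured in brackets; filled points passed camera with a preset correlation at adjusted p under 0.05, open points did not. LEA proteins and dehydrins lay highest, at 3.59 in Azucena and 4.94 in Bala; no list passed with an estimated correlation.

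The mean of both drought responses asked which genes changed over both cultivars, and gave 13165 called probe sets, 8045 higher and 5120 lower, and 7822 genes. The share of higher calls was 61.1% as deposited, 51.1% after quantile normalization, 47% after median centring and 65.6% after spike-in centring. In the mean, LEA and dehydrin genes rose in 7 of 8 cases (adjusted p = 1.3e-06; adjusted p = 0.5 with an estimated correlation). ABA signalling genes rose in 15 and fell in 2 of 20 cases, with 16 and 2 adjusted over the list alone (adjusted p = 6.9e-05; adjusted p = 0.64 with an estimated correlation). Heat shock genes rose in 23 and fell in 3 of 39 cases, with 23 and 4 adjusted over the list alone (adjusted p = 0.00041; adjusted p = 0.65 with an estimated correlation). HSP16.9A had a mean log2 change of 6.15, HSP18.1 of 6.48 and RAB16C of 5.17. Phytoalexin synthesis genes fell in 11 of 14 cases, led by CYP99A3 (adjusted p = 7.9e-05; adjusted p = 0.5 with an estimated correlation). Cytokinin genes fell in 12 and rose in 3 of 22 cases, with LOGL9 at -1.99 (adjusted p = 0.00039; adjusted p = 0.64 with an estimated correlation). Calcium-dependent kinases fell in 9 of 19 cases, with CPK4 at -1.86 (adjusted p = 0.00039; adjusted p = 0.64 with an estimated correlation). Jasmonate genes fell in 13 and rose in 2 of 26 cases, with 14 and 2 adjusted over the list alone and TIFY10B at -1.54 (adjusted p = 0.00039; adjusted p = 0.65 with an estimated correlation). The lists of iron homeostasis (12 of 25 lower, 5 higher, adjusted p = 0.023), photorespiration (4 of 5 lower, adjusted p = 0.044), calmodulin-like proteins (9 of 24 lower, 4 higher, adjusted p = 0.044) and WRKY factors (3 of 6 lower, 1 higher, adjusted p = 0.046) were called as well. Each had an adjusted p = 0.65 with an estimated correlation. Adjusted over the list alone the photorespiration list also had 1 gene higher. These 4 were not called under quantile normalization (0.061, 0.1, 0.065 and 0.1) or median centring (0.055, 0.055, 0.055 and 0.11). Leaving out 1 array also ended the call of the calmodulin-like list (Azucena control 2, Bala control 1, Azucena drought 2, Bala drought 2 or 3, adjusted p from 0.051 to 0.067). It ended that of the photorespiration list (Bala control 1 or 3, Azucena drought 1, 0.053 to 0.057) and of the WRKY list (Azucena control 2 or 3, Bala control 1 or 3, Azucena drought 2, Bala drought 2, 0.051 to 0.075).

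The 2 responses share no arrays, and across all 33476 probe sets, which are not independent replicates, their log2 changes correlated at r = 0.646 (Pearson) and 0.516 (Spearman). In both cultivars 2820 probe sets rose, where independent lists would share 983, and 2065 fell, where independent lists would share 484. A further 305 were called in both with opposite directions.

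The difference between the cultivars' drought responses was tested as an interaction, Bala response minus Azucena response. Among genes with a name, CHS1 showed the largest positive value, 6.25 (SE 0.26, adjusted p = 8.2e-10). Its signal was 2690 ± 700 in Azucena control and 2530 ± 210 in Azucena drought, against 33.5 ± 12 and 3520 ± 170 in Bala. HSP18.0 followed among genes with a name, at 4.7 (SE 0.39, adjusted p = 1.4e-06). Its control signal was 1790 ± 410 in Azucena against 31.2 ± 8.9 in Bala. The glutathione S-transferase gene GSTF1 (4.15) rose from 57.7 ± 20 to 1140 ± 340 in Bala and was 148 ± 35 and 128 ± 36 in Azucena. The 4-coumarate-CoA ligase gene 4CL2 (3.72), the metallothionein gene MT2C (3.54), the expansin gene EXPA6 (2.98) and the cellulose synthase gene CESA1 (2.81) were also more positive in Bala. HSP16.0 stood at 3.68 (SE 1, adjusted p = 0.025). Its call was lost when any 1 of 5 arrays was left out (Bala control 1 or 3, Azucena drought 3, Bala drought 1 or 2), with adjusted p between 0.057 and 0.072. It was also lost with an added 1 in place of 16 (2.48, adjusted p = 0.41) or without the filter on low values (adjusted p = 0.09). In the other direction salT stood at -4.84 (SE 0.73, adjusted p = 0.00041), with 2510 ± 2800 in Azucena drought and 40.9 ± 26 in Bala drought. RBBI3.3, a trypsin inhibitor gene, stood at -4.3, with 1050 ± 230 in Azucena drought and 28.2 ± 18 in Bala drought. The chitinase gene Cht-1 (-4.17), the isocitrate lyase gene ICL (-4.13), the melatonin synthesis gene ASMT1 (-3.88), pinA (-3.86), the metallothionein gene MT1B (-3.83) and the glutaredoxin gene GRXC10 (-3.66) were likewise lower in the Bala response.

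Among lists, cellulose synthesis had 10 of 13 genes with a more positive response in Bala and none with a more negative one, with a median 1.58 above that of all genes (adjusted p = 2.2e-06; adjusted p = 0.93 with an estimated correlation). Across all probe sets tested the median interaction was 0.11 as deposited, 0.014 after quantile normalization, -0.026 after median centring and 0.14 after spike-in centring. Of the leading cellulose genes CESA1, CESA6 (1.59) and CESA3 (1.8) rose in Bala, whereas BC1L9 (2.34) fell in Azucena, from 1260 ± 180 to 185 ± 15, and was 145 ± 20 and 113 ± 5.5 in Bala. Beside them, 6 of 12 vascular and secondary wall markers had a positive interaction and 2 a negative one (adjusted p = 0.4), and 4 and 2 of the 9 that are not also in the cellulose list. Of 22 genes commonly used as references 7 (11 adjusted over the list alone) were more positive in Bala and none more negative, among them GAPC3 (2.18), ACT2 (2.68), ACT1 (1.34) and TUBB1 (2.66) (adjusted p = 0.0055; adjusted p = 0.94 with an estimated correlation). Kinesins were more positive in 8 of 27 cases (16 adjusted over the list alone), with KIN14C at 1.58 (adjusted p = 0.021; adjusted p = 0.94 with an estimated correlation). Beside them, 1 of 9 histone and cell division genes was more positive and none more negative (adjusted p = 0.67). Osmoprotectant genes were more positive in 6 of 11 cases (7 adjusted over the list alone) and more negative in none (adjusted p = 0.021; adjusted p = 0.94 with an estimated correlation). This call was lost without Azucena control 1 (0.061). Among them INO1, of inositol synthesis (1.94), stood at 0.11 in Azucena and 2.05 in Bala, and RFS (1.93) at 1.6 and 3.53. TPP1, a trehalose phosphatase gene (2.15), fell in Azucena and lay at background in Bala. Beta-glucosidases were more negative in 4 and more positive in 1 of 23 cases (6 and 2 adjusted over the list alone), led by BGLU16 (-2.49) (adjusted p = 0.04; adjusted p = 0.94 with an estimated correlation). Of 5 germin-like genes GER6 (-2.54) and GER4 (-0.96) were more negative (adjusted p = 0.04; adjusted p = 0.94 with an estimated correlation). The call of GER4 was lost without Bala drought 2 (-0.9, adjusted p = 0.051), with an added 1 in place of 16 (0.2) and under spike-in centring (0.055). The beta-glucosidase and germin-like calls were lost under quantile normalization (adjusted p = 0.12 for both) and median centring (0.08 for both). Leaving out 1 array also ended the beta-glucosidase call (Azucena control 2, Bala control 1 or 2, Bala drought 1 or 2, adjusted p from 0.051 to 0.1). The germin-like call ended likewise (Azucena control 1, Bala control 1, Azucena drought 1 or 3, Bala drought 1, from 0.05 after rounding to 0.13).

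In all 3794 probe sets had a called interaction, 2434 positive and 1360 negative, and 2333 genes. The share of positive calls, 64.2% as deposited, was 50.5% after quantile normalization, 47.2% after median centring and 67% after spike-in centring. Of the 3794, 1531 were called in Bala alone, 1239 in Azucena alone, 630 in both in the same direction, 305 in both in opposite directions and 89 in neither.

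**Figure D3:**
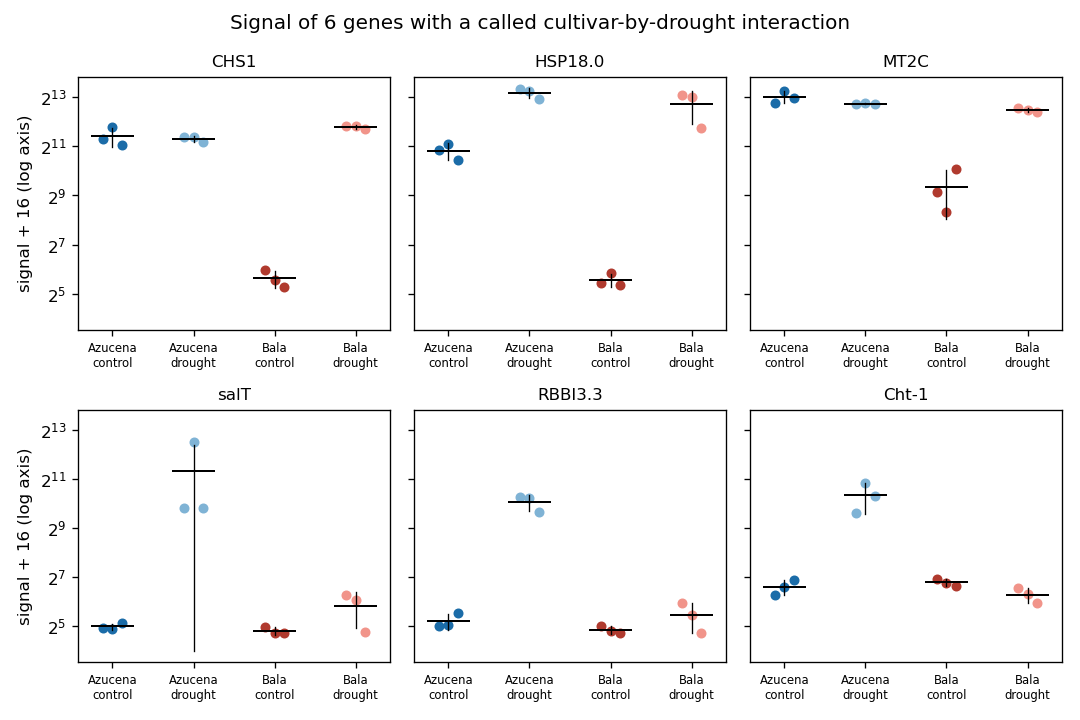
Signal plus 16 on a log axis for 6 genes with a called interaction; each point is 1 array, the horizontal line is the group mean and the vertical line ± 1 SD (n = 3), drawn no lower than a signal of 0. CHS1, HSP18.0 and MT2C were low in Bala control, and salT, RBBI3.3 and Cht-1 were high in Azucena drought.

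In flooded control plots Bala was compared with Azucena. An unnamed gene, LOC4347708, stood at -5.99 (log2) in Bala against Azucena. Among genes with a name, the largest differences were lower values in Bala, led by CHS1 (-5.77, adjusted p = 3.2e-13) and HSP18.0 (-5.25). Next were the calmodulin-like gene CML16 (-4.8), BURP17 (at least 24.0-fold lower) and HCT3 (at least 34.6-fold lower). The ammonium transporter gene AMT3-3 (-4.15), the autophagy gene ATG8D (at least 25.8-fold lower) and MT2C (-3.81) followed. Higher in Bala were the ethylene synthesis gene ACO1 (at least 12.3-fold, 388 ± 49 against 23.4 ± 22), the pyruvate phosphate dikinase gene PPDK2 (at least 9.12-fold), MAN7 (3.18), GRXC10 (at least 6.12-fold) and OsPP2C01 (2.76). So were the betaine aldehyde dehydrogenase gene BADH2 (2.68), RGLP1 (2.56) and Hd3a (2.5). Jasmonate genes were lower in Bala in 13 of 26 cases and higher in none, led by TIFY10C (at least 11.6-fold), a repressor of jasmonate response, and OPR10 (-2.3) (adjusted p = 0.0085; adjusted p = 1 with an estimated correlation). Cellulose synthesis genes were lower in 8 of 13 cases, led by BC1L9 (-2.98) (adjusted p = 0.014; adjusted p = 1 with an estimated correlation). Common reference genes were lower in 11 of 22 cases, including GAPC3 (-1.7), ACT2 (-2.37) and TUBB1 (-2.39) (adjusted p = 0.033; adjusted p = 1 with an estimated correlation). The call was lost without Azucena control 2 (0.069) or 3 (0.054) or Bala control 2 (0.063). In these arrays the background level averaged 15.3 in Bala control and 24 in Azucena control. There were 9572 called probe sets, 3327 higher and 6245 lower in Bala, and 5216 genes. The share higher in Bala, 34.8% as deposited, was 52.1% after quantile normalization, 60.8% after median centring and 22.1% after spike-in centring, with a median difference over all probe sets of -0.079, 0.044, 0.13 and -0.22. The direction in which most probe sets differed therefore depended on the scaling. Arrays did not overlap in 43.5% of the 15608 genes, against 10% by chance.

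Under drought, HSP16.0 (5.28, 2350 ± 1500 against 36.9 ± 17) and MADS14 (4.18, 841 ± 94 against 43.2 ± 41) were highest in Bala against Azucena among genes with a name. The laccase gene LAC15 (at least 7.12-fold), OsPP2C01 (3.11), EXPA6 (3), GSTF1 (2.98), RBM8 (2.86) and BADH2 (2.71) followed. Lowest were salT (-5.01), RBBI3.3 (-4.65), ASMT1 (at least 15.5-fold lower), HCT3 (at least 24.5-fold lower), the cellulose synthase-like gene CSLE1 (at least 26.4-fold lower), TIFY10C (at least 16.3-fold lower), Cht-1 (-3.97) and the cinnamyl alcohol dehydrogenase gene CAD8C (-3.85). Jasmonate genes were lower in Bala in 16 of 26 cases and higher in none, with TIFY11D at -1.67 (adjusted p = 7.9e-07; adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone 18 were lower and 1 higher. Pathogenesis-related genes, mostly chitinases, were lower in 6 of 11 cases (9 adjusted over the list alone), with Cht-1, Cht2 (-1.23) and Cht5 (at least 11-fold lower) (adjusted p = 0.0016; adjusted p = 0.55 with an estimated correlation). Phosphate starvation genes were lower in 8 of 18 cases (10 adjusted over the list alone), led by PHO1-2 (at least 6.98-fold) and PHT1-2 (-1.77) (adjusted p = 0.0033; adjusted p = 0.55 with an estimated correlation). Beta-glucosidases were lower in 8 and higher in 1 of 23 cases, led by BGLU16 (-3.29) (adjusted p = 0.0061; adjusted p = 0.55 with an estimated correlation). Of 7 metallothionein genes, a list added after names were seen, 4 were lower, led by MT4A (-2.22) (adjusted p = 0.029; adjusted p = 0.88 with an estimated correlation). Osmoprotectant genes were higher in 5 of 11 cases (6 adjusted over the list alone), led by INO1 (1.47) and BADH2 (2.71) (adjusted p = 0.029; adjusted p = 0.88 with an estimated correlation). The last call was lost without Azucena drought 3 (0.052). In all 7684 probe sets were called, 3623 higher and 4061 lower in Bala, and 4017 genes. The share higher, 47.1% as deposited, was 52.8% after quantile normalization, 58.6% after median centring and 33.9% after spike-in centring, with a median difference over all probe sets of 0.033, 0.056, 0.1 and -0.084. Arrays did not overlap in 43.9% of the 15608 genes, against 10% by chance.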

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

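Of the tests in this part, those of the genes level in drought, of the spike-in controls, of the scaling in Bala control, both tests on the cellulose genes and the splits with the mean response taken out were chosen after the result was seen. The test of probe set agreement in control and the other counts over splits of the arrays were set before. The demand that a value clear its bound by its spread was added after the first values were seen.

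What follows stood out because the 2 cultivars' drought responses differed by the interaction test, Bala response minus Azucena response on the log2 scale, with n = 3 arrays per group. It was called for 3794 probe sets. 6 gene lists differed, with a median over their genes of 1.73 for cellulose synthesis, 0.62 for common reference genes, 0.7 for kinesins, 0.87 for osmoprotectant and raffinose synthesis, -0.31 for beta-glucosidases and -0.57 for germin-like genes, none of them called with an estimated correlation (adjusted p = 0.93 or 0.94). The germin-like median is the value of GER3, which lay at background in all 4 groups and was not called. Of the genes named, 70 differed, 45 above 0 and 25 below. Of these, 16 had been picked as the largest interaction values. The other 54, named in the drought responses or as members of called lists, lay above 0 in 37 cases and below in 17. They include the members with the smallest p of the 6 lists called in the interaction, of which 4 were positive. This balance is thus partly set by the choice of genes. Over all called probe sets, 64.2% were positive as deposited and 50.5% after quantile normalization.

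Genes that rose in Bala and were not called in Azucena included CHS1 (6.25), GSTF1 (4.15), 4CL2 (3.72), HSP16.0 (3.68), MT2C (3.54), EXPA6 (2.98), CESA1 (2.81), TUBB1 (2.66), CESA4 (2.1), INO1 (1.94), CESA3 (1.8), CESA6 (1.59), KIN14C (1.58), KIN14F (1.54), TPP2 (1.24), KIN7F (1.06), KIN4A (1.06) and APX5 (1.01). Genes that rose in both cultivars, more in Bala, were HSP18.0 (4.7), HSP17.4 (2.15), BGLU1_LOC4333841 (1.99), RFS (1.93), KIN13B (1.33), BC1L6 (1.28), OsPP2C06 (0.87) and BADH1 (0.87). Another set fell in both, less in Bala, with mfs1 (2.65), ADF-11 (1.71), CML27 (1.59), MT2B (1.46), YSL16 (1.26), OPR10 (1.23) and HSFA4D (1.14). MADS14 (2.62), BC1L9 (2.34), TPP1 (2.15), CAD6 (1.97), VIT1 (1.45) and CYP76M7 (1.1) fell in Azucena and were not called in Bala. CAD3 (2.74), ACT2 (2.68), GAPC3 (2.18) and ACT1 (1.34) fell in Azucena and rose in Bala.

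Below 0, GRXC10 (-3.66) and BGLU16 (-2.49) rose in Azucena and fell in Bala. Genes that rose in Azucena and were not called in Bala were salT (-4.84), RBBI3.3 (-4.3), Cht-1 (-4.17), ICL (-4.13), ASMT1 (-3.88), pinA (-3.86), MT1B (-3.83), GER4 (-0.96) and BGLU5 (-0.74), and BGLU26 (-1.12) rose in both. Those that fell in Bala and were not called in Azucena were GER6 (-2.54), TIFY11B (-1.81), CPK2 (-1.69), CPK29 (-1.56), CPS2 (-1.51), BGLU20 (-1.47), CYP701A8 (-1.32) and CAT-A (-0.76). CAD8C (-2.04), MST3 (-1.74) and YSL13 (-1.16) fell in both, more in Bala.

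For genes at background under drought the interaction does not show which cultivar fell more. RGLP1 (-2.34), Hd3a (-1.82), LOGL10 (1.07) and NAS3 (2.05) fell to background in both cultivars, NAS3 in Azucena only in the mean of the arrays. With an added 1 in place of 16 the value of Hd3a was -0.27 (adjusted p = 0.86), that of LOGL10 1.17 (0.2) and that of NAS3 1.92 (0.21). CYP76M7 and TPP1 lay at background in Bala control, and CPK2, CPK29, CPS2 and GER6 in Azucena control, on all arrays or in the mean, so that a fall there was not measurable.

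The interaction calls of 13 of these genes were lost when 1 array was left out. For MST3 (-1.74) any array but Azucena drought 1 and Bala drought 3 did so (adjusted p from 0.07 to 0.11), for BGLU26 (-1.12) any but Bala control 2, Azucena drought 2 and Bala drought 1 (0.055 to 0.099), and for CYP701A8 (-1.32) any but Bala control 3, Azucena drought 1 and Bala drought 3 (0.069 to 0.13). For BGLU5 (-0.74) it was any but Azucena control 1, Bala control 1, Azucena drought 1 and Bala drought 3 (0.057 to 0.1), for LOGL10 (1.07) any but Azucena control 1, Bala control 2, Azucena drought 3 and Bala drought 1 (0.05 to 0.093), and for YSL16 (1.26) any but Azucena control 1, Bala control 2 and Bala drought 2 and 3 (0.051 to 0.088). OsPP2C06 was lost without Azucena control 2, Bala control 2, Azucena drought 3 or Bala drought 2 or 3 (0.052 to 0.069), KIN4A without Azucena control 2, Bala control 1, Azucena drought 3 or Bala drought 2 (0.052 to 0.067), HSP16.0 without Bala control 1 or 3, Azucena drought 3 or Bala drought 1 or 2 (0.057 to 0.072), and MADS14 without Azucena control 2 or Bala control 1 (0.06 and 0.063). Without Bala drought 2 the calls of GER4 (0.051), CAT-A (0.052) and YSL13 (0.061) were lost.

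The array was designed mostly on japonica rice sequence, so that probes which match Bala, an indica type, less well could make Bala look lower. If so, other probe sets of a gene called between the cultivars should share its direction less often than those of a gene called under drought, and the share lay -4.6 percentage points from the lower drought response in control (SE 1.6) and -5.5 in drought (SE 1.7), both within 1 SE of the bound of 5 points set for excluding it. Of the 360 genes over 4-fold lower in Bala control, 29 had a called interaction and rose in Bala above background to within 0.5 (log2) of Azucena. The test allowed for 18, which is 0.05 of the 360. That bound was a choice and not a count expected under mismatch. Measured against it, the count of 29 argues against mismatch alone for these genes as a set, not for each gene. The 360 were chosen by the same Bala control arrays that enter the rise, which favours a rise. Mismatch stays open for the others, of which 23 were level in drought without such a rise and 183 were over 4-fold lower in both conditions. A difference between the cultivars in expression itself stays open as well and was not tested apart from this.

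In control plots more probe sets were called lower than higher in Bala. Dimmer Bala control arrays stay open, because the spike-in controls lay 0.15 above those of Azucena control (SE 0.14), against -0.079 for the median of all probe sets tested, but only 0.05 above without Bala control 3 (SE 0.13) and 0.061 without Azucena control 3 (SE 0.12). Scaling between arrays as deposited cannot be told apart from a true excess of lower transcripts in Bala, since quantile normalization and median centring, which brought the share of lower calls from 65.2% to 47.9% at most, remove such an excess where it exists. Centring on the spike-in controls moved the share the other way, to 77.9%.

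Of 13 cellulose synthesis genes 10 had a more positive drought response in Bala, a list called with adjusted p = 2.2e-06 (adjusted p = 0.93 with an estimated correlation). Between the cultivars 8 were lower in Bala in control (adjusted p = 0.014, not called with an estimated correlation). In drought 6 were higher and 1 lower, a list not called (adjusted p = 0.27). The rise in Bala, the interaction and the control difference all use the same Bala control arrays, so they are not independent results. A larger share of secondary wall tissue in the droughted Bala leaves would raise CESA4, CESA7, CESA9 and the laccases most, and the median interaction of the other CESA genes was 1.1 higher (1.76 over 6 genes against 0.671 over 8), with a bootstrap SE of 1.1, so that this source cannot be told apart. More dividing tissue would raise histone and cell division genes. Their median interaction was 0.14 of that of the cellulose genes (SE 0.12), within 1 SE of the bound of 0.25. More dividing tissue therefore stays open for lack of genes. Whether the kinesins that rose in Bala reflect dividing cells was not tested. Nor was a difference in tissue between the control leaves of the cultivars. A difference in wall synthesis between the cultivars, in control leaves or in drought, is likewise an open hypothesis.

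Other splits of the arrays within both cultivars were drawn, 100 of 200 possible. For the mean response 1 of 100, the real one, gave as many as 13165 calls, and the highest other gave 4068. That share lay under 0.05. Other splits carry the real drought response as spread within groups, which lowers their counts. The real grouping thus stood out in its count of calls, which does not exclude chance for any single probe set. For the interaction 4 of 100 gave as many as 3794, and the highest other gave 13165. The 3 other splits swap drought and control wholly or mostly in Bala and so carry the shared response into the interaction, a structure of the samples, and this count does not show whether chance is excluded. With the mean response taken out of each probe set first, 1 of 100, the real one, gave as many as 3813 calls. The highest other gave 1. The response taken out was that of the real grouping, so the split that swaps all of Bala had 0 calls by construction. Other splits carried the real interaction as spread within groups. That test therefore cannot show whether chance is excluded either. For the 4 comparisons of 3 against 3 arrays, 10 splits cannot give a share under 0.05. The real split, 1 of 10, gave 9190 calls in Azucena, 10567 in Bala, 9572 between the cultivars in control and 7684 in drought, and the highest other gave 0 in each.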

How the results depend on the processing

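Centring on the spike-in controls was chosen after seeing the data, and the other alternatives were planned. Every count of called probe sets stayed within 1.5 times the reported one under every setting but testing 1 probe set per gene, where fewer are tested and 5978 were called in Azucena, 6899 in Bala, 8232 in the mean, 5499 between the cultivars in control and 4215 in drought. Over the other alternatives counts reached 10630, 11516, 13941, 11410 and 9565, the interaction ranged from 2738 to 4678, and the correlation of the responses from 0.586 to 0.664. Leaving out 1 array at a time gave 7321 to 9713 calls in Azucena, 7998 to 10602 in Bala, 11585 to 13124 in the mean, 2600 to 3900 in the interaction, 7738 to 9587 between the cultivars in control and 5853 to 8026 in drought, and a correlation of 0.62 to 0.66. Called lists then numbered 11 to 15, 15 to 17, 8 to 13, 4 to 9, 2 to 4 and 5 to 6 in the same order, 49 to 59 in total. With an estimated correlation camera called 0 lists in each of the 6 contrasts and 0 in total, with a lowest adjusted p of 0.62, 0.48, 0.5, 0.93, 1 and 0.55. Fry, which asks whether the genes of a list move one way and not whether they differ from other genes, called 26 in Azucena, 30 in Bala, 33 in the mean, 9 in the interaction, 18 between the cultivars in control, 14 in drought and 130 in total.

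With the replicate number as a block, 9440, 10790, 13420, 4039, 9800 and 7851 probe sets were called. These counts were higher than without the block in all 6 contrasts. Same-numbered arrays correlated at -0.11 to 0.22 in their deviations from group means, and 6 of 12 correlated best with their own number. With only 3 numbers to choose from, some arrays would match their own by chance. The highest values, 0.17 and 0.22, were between the drought groups of the 2 cultivars, for numbers 1 and 3. Whether the numbers pair the arrays thus stays open, and the main model has no term for it. Of the named gene results called, 70, 71, 57, 70, 28 and 37 in the 6 contrasts, 1, 0, 2, 22, 0 and 2 lost the call under some setting and 0 changed direction. In the mean response GLO1 lost it without 8 of the arrays (adjusted p from 0.052 to 0.14) and WRKY9 without 7 (0.05 after rounding to 0.071). Between the cultivars in drought MT2B lost it without Azucena drought 2 or Bala drought 1 (0.17) and P5CS1 without Bala drought 1 (0.051). In the interaction, an added 1 in place of 16 ended the calls of KIN14F (0.11), Hd3a (0.86), CYP76M7 (0.21), OPR10 (0.057), NAS3 (0.21), CPS2 (0.065) and CPK29 (0.059), and an added 64 those of HSP17.4 (0.2) and BC1L6 (0.069), none of which was lost by leaving out an array. The causes were not tested. Signal near background limits dim genes most, since the added value then sets much of their change.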

Other observations

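Further lists, set out beforehand or added after gene names were seen, were tested with camera like the others. From water channels to seed storage proteins none passed the threshold in the comparisons given here. Water channel genes (aquaporins, 20 measured) rose in 2 and fell in 6 cases in Azucena (camera, adjusted p = 0.3), and rose in 7 and fell in 3 in Bala (adjusted p = 1). In control plots they were lower in Bala in 11 cases and higher in 1 (adjusted p = 0.15). Of 8 photosystem and light-harvesting genes 4 fell and none rose in Azucena (adjusted p = 0.18), and 3 fell and 2 rose in Bala (adjusted p = 0.25). Drought-linked transcription factor genes, 15 in all, rose in 5 and fell in 2 cases in Azucena (adjusted p = 0.36) and rose in 4 and fell in 4 in Bala (adjusted p = 1). Auxin response genes rose in 14 and fell in 4 of 42 cases in Azucena (adjusted p = 0.24) and rose in 12 and fell in 5 in Bala (adjusted p = 0.54). Gibberellin synthesis and breakdown genes fell in 5 of 7 cases and rose in 1 in Azucena (adjusted p = 0.06), and flowering genes fell in 5 of 10 and rose in 1 (adjusted p = 0.061). In Bala CIPK kinase genes rose in 12 of 23 cases and fell in 1 (adjusted p = 0.058), and FtsH and Clp plastid protease genes rose in 7 of 14 and fell in none (adjusted p = 0.13). Seed storage protein genes, markers of panicle tissue, rose in none and fell in 1 of 5 cases in both cultivars (adjusted p = 0.46 in Azucena and 0.35 in Bala).

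Several lists were called in 1 cultivar and not in the other, and the interaction test showed no difference between the cultivars for them. This held for chlorophyll synthesis (adjusted p = 0.27), lignin synthesis (0.99), chlorophyll breakdown and leaf senescence (0.35), antioxidant enzymes (0.089), photorespiration (0.51), WRKY factors (0.28) and calmodulin-like proteins (0.47). A p that misses the threshold does not show that the responses were alike.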
